A study of Mus musculus with 17 samples.

How the data were processed

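RNA was measured in 17 libraries of sorted mouse multipotent progenitors of the MPP2 type. The labels define these as lineage-negative, Sca-1-positive and c-Kit-positive cells with CD48 and CD150 on their surface. Each library was made from 100 cells of bone marrow (BM) or mesenteric lymph node (MLN) after 7 days of plain water (ddW) or 2.5% dextran sulfate sodium (DSS) as drink. The labels give 4 BM-ddW, 3 BM-DSS, 6 MLN-ddW and 4 MLN-DSS libraries and do not say whether each came from a separate animal, so the p-values measure the spread between these libraries only. Complementary DNA was primed with not-so-random primers, and libraries were prepared with a transposase kit.

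The submitters' processing notes name Trim Galore 0.4.3, STAR 2.5.3a, featureCounts without a version, and genome build GRCm38, without their order or options. The deposited files hold one signal value per gene and library. In every library 100% of the deposited values were whole multiples of one step, at a tolerance of 0.001, so each value is a read count divided by one size factor of that library. How the authors computed the size factors is not stated. Each file lists the same 4997 genes in the same order, and the rule that chose them is not stated. Names of 4 of these had been turned into dates and were left out, which left 4993; they held 0.00195% to 0.0119% of the reads of a library.

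The design fixed before the data were examined assumed raw counts and named limma as the test for normalised values. The values being normalised, limma 3.58.1 (R 4.3.3) with an intensity trend was fitted to log2(value + 1), in one model with a mean for each of the 4 groups, over the 4344 genes with a value of at least 10 in at least 3 libraries. Log2 differences of that scale understate folds of weakly read genes. P-values are two-sided and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The comparisons were DSS against ddW in each tissue, MLN against BM with each drink, and the interaction of tissue and DSS. The quasi-likelihood test of edgeR 4.0.16 with TMM factors, on the whole reads recovered from the values, tested 4302 genes and served as an alternative chosen after the unit was known. So were TMM and RLE scaling in limma, a filter of at least 50 in 3 libraries, and other pseudocounts for the lists. The edgeR fit had a common biological coefficient of variation of 0.302. Other alternatives were other pseudocounts, filters and scalings, the Wald test of DESeq2 1.42.0, limma-voom, a model of only the groups compared, replicate numbers as blocks, genes detected as a covariate, and each library left out in turn. The labels do not say whether replicate numbers pair libraries across groups. Residual profiles of libraries with the same number had correlations from −0.0376 to 0.189, and from 0.00146 to 0.189 for DSS against ddW. Libraries with different numbers were not compared, so these values cannot decide on pairing. The blocked fits stand only among the alternatives.

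For 38 gene lists fixed before the data were examined, members that changed were counted with adjustment over all genes tested and adjusted over the list alone. The 21 lists with at least 5 tested members were tested with camera, with a preset correlation of 0.01 and adjustment over the lists of a comparison; an estimated correlation and fry were alternatives. Marker lists of other cell types were scored per library as the mean of log2(value + 1) and compared by exact permutation tests, two-sided, adjusted over 8 lists. Named genes were, per comparison, the 10 with the highest and the 10 with the lowest log2 difference among those past the threshold with a group mean of at least 10 CPM, without predicted gene models, and up to 4 members with the smallest p of each list that passed or held a changed member; lowest ranks were left out for length, and some genes that the rule names are not reported here. Kit, Ly6a, Cd48 and Slamf1, also named by the rule, were not analysed here because none is among the listed genes. Genome positions came from GENCODE M21 by symbol, which matched 4928 genes, or 98.62%; 143 of these matched through an older symbol. Whether reads were counted by strand is not stated, so values of genes that overlap others on the opposite strand are uncertain.

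Values are means ± SD of the groups, and log2 differences are given ± SE of the model. Reads over the listed genes ranged from 301956 to 1808673 per library. This is a part of each library and not its depth. A floor of 3 reads per library corresponded to a mean value of 3.73 in BM-ddW, 3.08 in BM-DSS, 2.75 in MLN-ddW and 3.12 in MLN-DSS, and folds against groups without any read are bounds against that floor. Floors cover counting error only, since reads of amplified libraries are not independent molecules. The analysis was tested on simulated data with 200 changed genes. Of genes changed by a factor of 4, it recovered 80.8% for MLN-DSS against MLN-ddW, 69.5% for BM-DSS against BM-ddW, 79.8% for MLN-ddW against BM-ddW and 70.1% for MLN-DSS against BM-DSS, and at a factor of 2 it recovered 47.4%, 33.0%, 38.1% and 28.1%. False calls made up 4.62% to 8.93% of calls. A planted list, with members raised by a factor of 4, passed in each of the 4 comparisons. Beside it, 1 other list passed in BM-DSS against BM-ddW and 1 in MLN-ddW against BM-ddW. Lists with smaller changes were not simulated. The simulation drew genes independently, used the size factors without error and, between tissues, changed only the chosen genes and the planted list. In the data neighbouring genes differed together, and 3791 and 3133 genes were called between tissues, so these shares may not carry over. Permutations and other statistics used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.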

Results

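MPP2 cells are multipotent progenitors of the blood system, and the study asked how such cells respond when the gut is injured. DSS damages the colon epithelium and causes colitis, and the mesenteric lymph node drains the gut. Reads over the listed genes ranged from 359737 to 471289 in the 7 BM libraries and from 301956 (MLN-ddW 1) to 1808673 (MLN-ddW 5) in the 10 MLN libraries. The first principal component held 72.0% of the variance and separated the tissues, and the next components (6.01% and 4.64%) spread the MLN libraries. Across genes, Spearman correlations between libraries were 0.929 to 0.971 within BM, 0.868 to 0.963 within MLN and 0.576 to 0.695 between the tissues. The listed genes were chosen in a way tied to tissue: 99.8% had a p under 0.05 in a DESeq2 test of MLN against BM. The separation of the tissues and the lower correlations between them are therefore largely built in. MLN-DSS 3 stood apart, with 23.4% of genes at 0 against 8.37% to 15.6% in the other libraries and a second component score of −72.7. Genes with a read numbered 4221 ± 267 in MLN-DSS (n = 4) and 4503 ± 76.7 in MLN-ddW (n = 6; exact permutation p = 0.0190, two-sided). Neighbouring genes differed together and ribosomal protein genes were low (Other observations). In all comparisons below, a value therefore need not measure the messenger of the named gene alone.

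**Figure D1:**
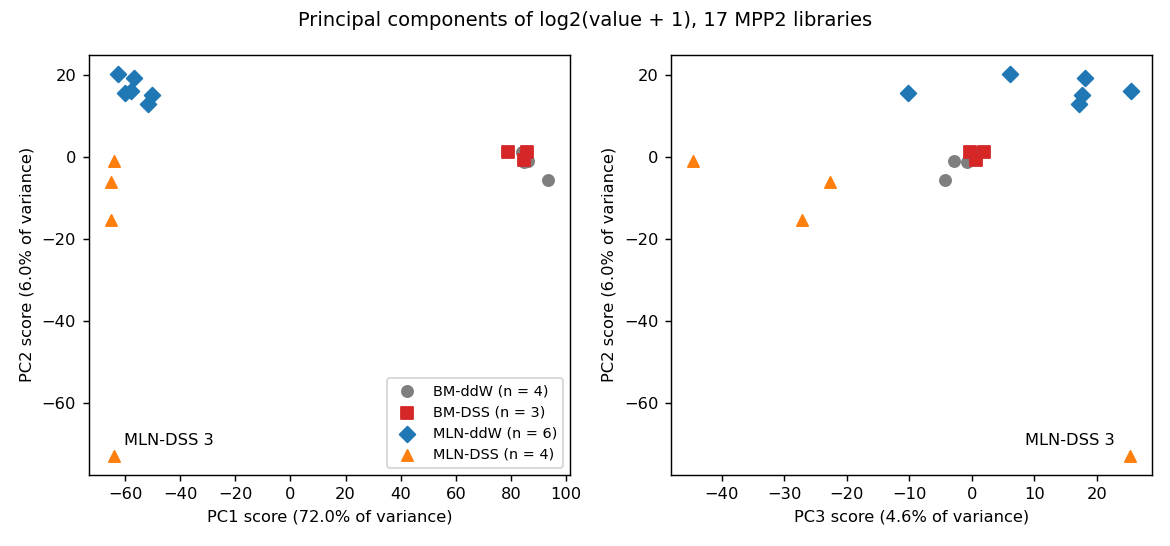
Scores of the 17 libraries on the first 3 principal components of log2(value + 1), with the share of variance on each axis; each point is a library and colours are groups. BM and MLN separate on the first component, and MLN-DSS 3 has the lowest score on the second (−72.7). The listed genes were chosen in a way tied to tissue, so the separation of BM and MLN is largely built in.

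Cd86, a costimulatory ligand of antigen-presenting cells, rose from a normalised read count of 106 ± 21.9 in MLN-ddW (n = 6) to 523 ± 343 in MLN-DSS (n = 4), a log2 difference of 2.01 ± 0.36 (limma, adjusted p = 0.00177). Stat3, which transmits IL-6 signals, rose from 224 ± 77.7 to 515 ± 191 (1.20 ± 0.29, adjusted p = 0.0150). Nfkbiz, an NF-kB cofactor, rose from 243 ± 36.8 to 535 ± 171 (1.08 ± 0.21). Tlr2, a receptor of bacterial lipoproteins, rose from 60.3 ± 11.6 to 123 ± 29.1 (1.01 ± 0.24), and Birc3, an inhibitor of apoptosis, from 856 ± 144 to 1427 ± 359 (0.72 ± 0.15). Il1r1, the receptor of interleukin 1, fell from 133 ± 47.5 to 34.1 ± 24.7 (−2.21 ± 0.52, adjusted p = 0.0120). The call of Stat3 ended without MLN-DSS 1 (adjusted p = 0.0530) and, with that of Birc3, with only these groups in the model (0.0635 and 0.0520). The call of Il1r1 ended with pseudocount 0.1 (0.145) and with genes detected as a covariate (0.0907), as did that of Tlr2 with the covariate (0.103).

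The largest increases were in Crtc2, a coactivator of CREB, from 2.32 ± 2.84 to 52.6 ± 38.02 (4.09 ± 0.70), and Kif4, a mitotic kinesin, from 84.6 ± 153 to 410.3 ± 71.0 (3.54 ± 0.60). Kif4 was at 395 in MLN-ddW 1, within the MLN-DSS range of 330 to 503, and at 12.97 to 39.1 in the other MLN-ddW libraries. Ccm2 rose from 1.25 ± 1.83 to 15.3 ± 5.91 and Scn3b from 23.3 ± 7.28 to 290.1 ± 228. Atp5l rose from 0.697 ± 0.715 to 10.8 ± 6.07 and Fxyd6 from 11.7 ± 15.1 to 88.0 ± 58.8. The call of Fxyd6 ended without MLN-DSS 1 (adjusted p = 0.0596), without MLN-DSS 2 (0.0709), in DESeq2 (0.0820), with pseudocount 0.1 (0.0587), with only these groups in the model (0.132) and in robust edgeR (0.0671), which also ended that of Kif4 (0.0589). The call of Scn3b ended with pseudocount 0.1 (0.0806) and with only these groups in the model (0.0548). The largest decrease was in Arpp21, a phosphoprotein of the RNA-binding kind that is known from neurons and thymocytes, from 172 ± 101 to 0.279 ± 0.558 (−6.54 ± 0.82, adjusted p = 9.4e-05). Ipcef1 fell from 44.2 ± 10.99 to 0.558 ± 1.12 and Slc6a20a from 57.0 ± 12.7 to 2.83 ± 3.28. Arhgap17 fell from 69.1 ± 34.1 to 3.06 ± 3.63 and Heatr1, a factor of ribosome assembly, from 35.1 ± 25.2 to 2.66 ± 4.68. In MLN-ddW 1, Arhgap17 was at 6.28, below MLN-DSS 1 at 7.81, with the other MLN-ddW libraries at 60.0 to 98.4. Arpp21 was at 6.28 in MLN-ddW 1 as well, with the other MLN-ddW libraries at 89.4 to 256. Tex15 had no read in MLN-DSS, at least 10.0-fold below its MLN-ddW mean of 31.4 ± 33.1. Limma-voom with sample quality weights ended the calls of Arpp21 (0.0611) and Tex15 (0.0693), and genes detected as a covariate that of Arhgap17 (0.0535).

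Of the fixed lists, MHC class II and antigen presentation moved up: 1 of its 5 tested members rose over all genes tested (Cd86), and 2 rose adjusted over the list alone (camera adjusted p = 0.00838; adjusted p = 0.1002 with an estimated correlation). Cd80, the other ligand of CD28, was at 52.1 ± 19.5 and 171 ± 92.6 (1.53 ± 0.48, adjusted p = 0.0567). H2-Aa was at 244 ± 33.9 and 473 ± 178 (0.88 ± 0.41, adjusted p = 0.212), and Ciita, the regulator of class II genes, at 1104 ± 146 and 1703 ± 816 (0.51 ± 0.29, adjusted p = 0.324). In edgeR the adjusted p was 0.00526 for Cd80 and 0.0304 for H2-Aa. The list did not pass without MLN-DSS 4 (adjusted p = 0.0615).

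None of the other 20 lists passed camera. Members that rose were 2 of 7 in the NF-kB and TLR inflammatory list (Nfkbiz and Birc3; 2 rose and 1 fell adjusted over the list alone) and 1 of 6 among TLR receptors and signalling (Tlr2; 2). They were also 2 of 5 among immediate early and dissociation stress genes (Klf6, from 258 ± 67.4 to 642 ± 177, and Nfkbiz; 2), and the 1 tested of the IL-6 and STAT3 response (Stat3; 1). One member each rose among 6 of the p53 response (Eda2r) and 9 nuclear genes of oxidative phosphorylation (Atp5l); over the list alone these counts were 2 with 1 lower, and 1. Members that fell were 1 of 8 monocyte and macrophage genes (Cd68, from 21.03 ± 10.999 to 3.25 ± 2.23), 1 of 2 eosinophil genes (Ccr3, from 37.5 ± 15.996 to 10.7 ± 6.27) and 1 of 10 cytokine and growth factor receptors (Il1r1). Also lower were 1 of 15 S phase genes (Dscc1, from 12.4 ± 7.04 to 3.05 ± 4.73) and 1 of 3 endothelial genes (Kdr, from 38.9 ± 15.04 to 13.04 ± 5.58). So were 1 of 8 cytosolic ribosomal protein genes (list median −0.57) and 1 of 8 of cholesterol synthesis. Each of these counts was the same adjusted over the list alone. In the glycolysis list 1 of 8 fell (Hk1, from 23.8 ± 7.09 to 8.80 ± 5.32; 2 over the list alone). Of 14 G2 and M phase genes, Top2a, a topoisomerase of dividing cells, rose from 362 ± 96.6 to 982 ± 448, and Kif2c fell from 37.5 ± 18.5 to 5.19 ± 3.19 (1 each over the list alone). Among these lists, median and mean differed in sign in the NF-kB list (−0.05 and 0.01), the p53 list (−0.24 and 0.35) and the endothelial list (0.06 and −0.39). No member passed among 6 genes of HSC and MPP identity, 5 of neutrophils, 6 erythroid, 6 megakaryocyte, 9 of the interferon response, 8 of migration and 7 of ribosome biogenesis. Over the list alone 1 erythroid and 1 interferon gene fell. The calls of Ccr3 ended without MLN-DSS 2 or 3 (adjusted p = 0.0576 and 0.0651), of Dscc1 without MLN-DSS 2 (0.0585). Those of Eda2r ended without MLN-DSS 1 or 4 (0.0543 and 0.0550), and that of Top2a without MLN-ddW 2, 3, 4 or 6 or MLN-DSS 1, 2 or 4 (0.0513 to 0.123). With genes detected as a covariate the adjusted p was 0.284 for Ccr3, 0.292 for Dscc1, 0.294 for Hk1 and 0.0535 for Eda2r. With only these groups in the model the calls of Ccr3 (0.0697), Dscc1 (0.111), Kdr (0.0504), Hk1 (0.0970), Top2a (0.0803) and Eda2r (0.101) ended as well.

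In all, 302 of 4344 genes passed, 99 higher and 203 lower with DSS, and 958 had an unadjusted p under 0.05. With TMM scaling in limma, 21.4% of 295 calls were higher instead of 32.8%. The excess of lower calls depended on how the number of genes detected was treated: with genes detected as a covariate, 157 genes were higher and 101 lower, the opposite way. The edgeR test called 339 genes (101 higher, 238 lower), of which 250 were shared in the same direction. The count was 155 with only these groups in the model, 476 in DESeq2 and 501 in limma-voom. Without MLN-DSS 3 it was 403, of which 248 were among the 302, and the directions were nearly even (199 higher, 204 lower). None of the 8 marker lists of other cell types differed by exact permutation tests. The T cell score came closest, at 5.89 ± 0.38 in MLN-DSS and 6.405 ± 0.20 in MLN-ddW (exact permutation p = 0.0476, adjusted 0.381), and 1 list had an unadjusted p under 0.05. Each score rested on only 2 to 5 listed genes (3 for T cells), so these tests cannot exclude a change in other cell types.

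Several of the lowered genes lay side by side on chromosome 4 (GRCm38), a run singled out after its values were seen. Between 116221618 and 117914999, 8 of the 17 tested genes reported here fell in MLN-DSS. The 8 were Zswim5, Urod, Hectd3, Eif2b3, Btbd19, Tctex1d4, Plk3 and Kif2c. Eif2b3, a subunit of the translation initiation factor eIF2B, fell from 71.0 ± 35.7 to 2.79 ± 3.59. Btbd19 fell from 44.9 ± 25.5 to 3.45 ± 4.33. Hectd3 had no read in MLN-DSS, at least 7.03-fold below its MLN-ddW mean of 22.0 ± 12.2. One ddW library, MLN-ddW 1, was near the MLN-DSS level at 4 of them, with Hectd3 at 0, Eif2b3 at 6.28, Kif2c at 6.28 and Btbd19 at 10.98, so low values in this run were not confined to DSS. In BM the same 8 genes had log2 differences with DSS of 0.63 (Btbd19) to 1.09 (Tctex1d4), with adjusted p from 0.288 to 0.773.

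**Figure D2:**
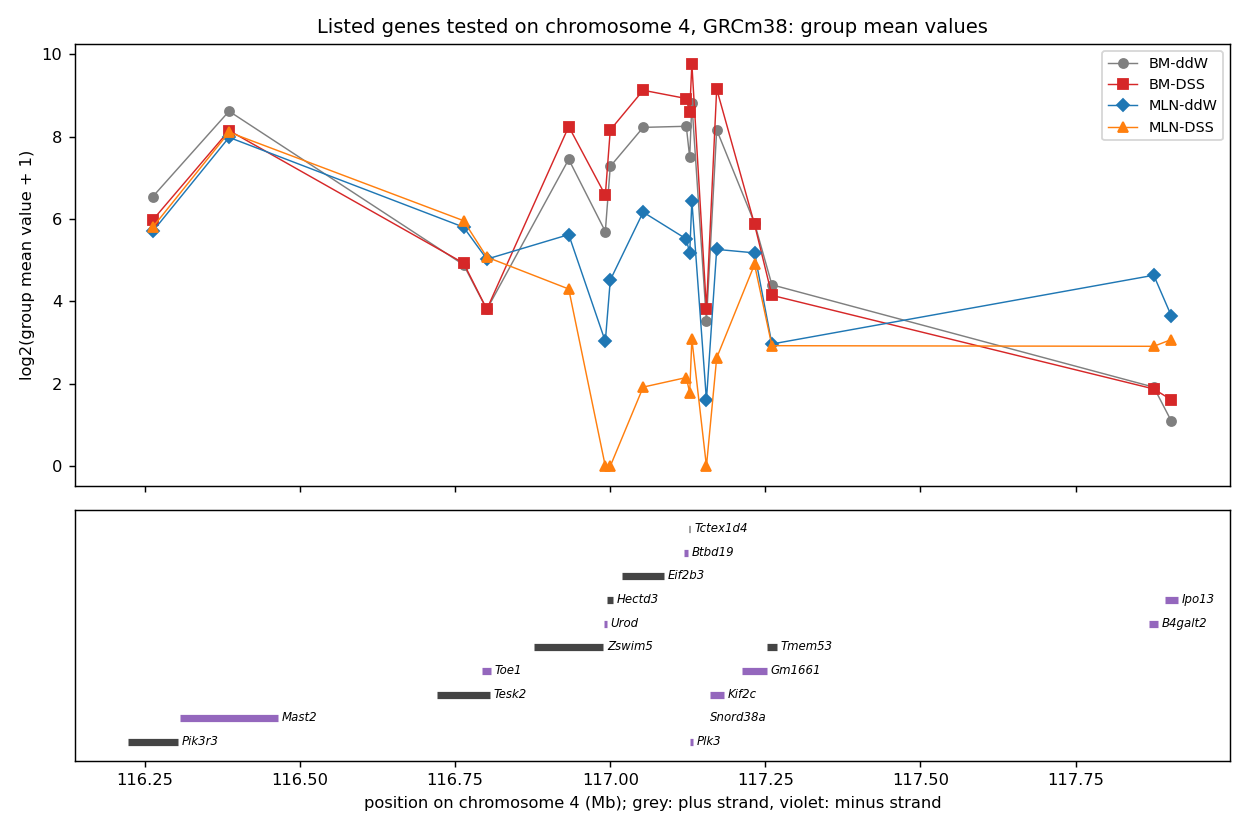
Mean value of each group on a log2 scale (upper panel) at the listed genes tested on chromosome 4 between 116221618 and 117914999, with gene positions by strand (lower panel); points are group means. From Zswim5 to Kif2c the MLN-DSS means lie below the other groups, and from Pik3r3 to Toe1 the means of the MLN groups lie close together.

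For the number of genes changed with DSS in bone marrow, chance was not excluded (Other observations). In bone marrow (BM-DSS, n = 3, against BM-ddW, n = 4), Il1r1 rose with DSS from 1.36 ± 1.94 to 17.6 ± 4.64 (3.29 ± 0.62, adjusted p = 0.00632) and Nfkbiz from 113 ± 16.7 to 297 ± 105 (1.34 ± 0.25, adjusted p = 0.00632). Pgm2l1, an enzyme that makes sugar bisphosphates, rose from 0.335 ± 0.670 to 34.4 ± 11.9 (4.77 ± 0.46, adjusted p = 6.5e-06), and Cinp, a cell cycle checkpoint protein, from 0.249 ± 0.497 to 23.1 ± 14.2. Dram2, a lysosomal membrane protein, rose 7.88-fold from 17.5 ± 13.9 to 138 ± 32.6, and P3h3 from 3.77 ± 2.86 to 37.4 ± 16.99. Rif1, a regulator of replication timing, rose from 1.27 ± 1.13 to 18.2 ± 10.8, and Mpzl3 from 2.56 ± 2.03 to 20.5 ± 6.22. Neurod2 fell from 18.3 ± 18.9 to 2.44 ± 1.72, Wnk4 from 170 ± 48.0 to 72.6 ± 5.34 and Slc23a2, a transporter of vitamin C, from 613 ± 77.2 to 289 ± 60.9.

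Cytokine and growth factor receptors were higher as a list: 1 of 10 rose over all genes tested (Il1r1) and 2 adjusted over the list alone (camera adjusted p = 0.00616; adjusted p = 0.0861 with an estimated correlation). Il10rb was at 54.1 ± 2.54 and 90.1 ± 12.7 (0.72 ± 0.20, adjusted p = 0.0967). Ifnar1 was at 339.7 ± 45.9 and 448 ± 28.8 (0.41 ± 0.16, adjusted p = 0.249) and Csf1r at 11.8 ± 2.04 and 40.5 ± 12.3 (1.67 ± 0.87, adjusted p = 0.426). Other list members that rose were Nfkbiz, 1 of 7 in the NF-kB and TLR list (2 adjusted over the list alone) and 1 of 5 immediate early genes (1). H2-Aa, 1 of 5 in the MHC class II list (1), rose from 0.342 ± 0.684 to 6.94 ± 6.03, and Lss, lanosterol synthase, 1 of 8 cholesterol synthesis genes (1), from 3.95 ± 4.57 to 28.4 ± 8.64. None of these lists passed camera.

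In all, 52 genes passed, 43 higher and 9 lower with DSS in BM, and 570 had an unadjusted p under 0.05. Of 35 splits of the BM libraries into groups of the same sizes, 2 gave at least 52 genes, the real one included. The other gave 77, so chance was not excluded. In edgeR 42 genes passed (35 higher, 7 lower), of which 40 were shared. The count was 14 with only these groups in the model, 114 in DESeq2 (67 higher, 47 lower), 129 without BM-ddW 1 (73 higher, 56 lower), 22 without BM-DSS 1 and 25 without BM-DSS 2. Limma-voom with sample quality weights called 452 genes, with more lower than higher (178 higher, 274 lower). Calls that ended without 1 library were those of Il1r1 (adjusted p = 0.0590) and Nfkbiz (0.0760) without BM-DSS 2, H2-Aa without BM-ddW 2, BM-DSS 1 or BM-DSS 2 (0.0522, 0.127 and 0.148) and Lss without BM-ddW 4 (0.0569). The same held for Neurod2 without BM-DSS 1 or 3 (0.0756 and 0.0779), Wnk4 without BM-ddW 2 or BM-DSS 1 (0.0508 and 0.0981) and Slc23a2 without BM-DSS 1 (0.0756). The adjusted p in edgeR was 0.0753 for H2-Aa, 0.194 for Lss and 0.0624 for Neurod2. With only these groups in the model, the calls of Il1r1, Nfkbiz, Dram2, P3h3, Rif1, Mpzl3, Neurod2, Wnk4, Slc23a2, H2-Aa and Lss ended, with adjusted p from 0.0797 (Slc23a2) to 0.189 (Neurod2). In limma-voom those of Il1r1 (0.151), P3h3 (0.0969), Rif1 (0.117), Neurod2 (0.374) and H2-Aa (0.355) ended. The groups of 3 and 4 cannot give an exact permutation p under 0.0571, so marker lists of other cell types could not pass. The lowest p was 0.171, for the NK and innate lymphoid score.

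A test of the interaction asked whether DSS acted alike in the tissues. Across the 4344 genes, which are not independent replicates, the DSS differences of BM and MLN had a Pearson correlation of 0.00314 and a Spearman correlation of 0.0315, with jackknife SE over libraries of 0.0459 and 0.0712. The listed genes were chosen in a way tied to tissue. Pgm2l1 and Cinp had no read in MLN, and Ccm2, Fxyd6 and Atp5l none in BM, so no DSS effect could be seen there. A low correlation, and some interaction calls, may therefore be partly built in. Of 8 genes called in both tissues, 5 rose in both (Stat5b, Sun2, Nfkbiz, Frs3 and Fam53b; 0.980 expected if the calls were independent), and Il1r1, Rhof and P3h3 fell in MLN and rose in BM. The interaction passed for 125 genes, 29 with a higher and 96 with a lower DSS effect in MLN than in BM (769 at an unadjusted p under 0.05). In edgeR 106 passed, of which 90 were shared. Among them were Il1r1 (interaction −5.51 ± 0.81, adjusted p = 9.0e-04) and P3h3 (−4.77 ± 0.70, adjusted p = 9.0e-04). Others were Cd86 (2.90 ± 0.56, adjusted p = 0.00780), which was at 27.9 ± 4.44 in BM-ddW and 15.6 ± 8.20 in BM-DSS, and Tmem57 (2.30 ± 0.37, adjusted p = 0.00194). Eif2b3, Kif2c and Glg1 also had lower effects in MLN, at −5.25 ± 0.94, −3.53 ± 0.68 and −5.18 ± 0.98. None of 21 lists passed camera for the interaction, and 769 genes had an unadjusted p under 0.05. Fry, which asks only whether a list moves one way, passed 2 lists: cytokine and growth factor receptors and G2 and M phase genes, both lower (adjusted p = 0.0111 each). The count of 125 was 228 in DESeq2, 81 without BM-ddW 3, 37 without BM-DSS 1, 57 without BM-DSS 2, 64 without BM-DSS 3 and 234 without MLN-DSS 3. With genes detected as a covariate the directions turned (53 higher, 41 lower), and the calls of Kif2c (adjusted p = 0.0781) and Glg1 (0.0509) ended. The call of Cd86 ended in limma-voom (0.216).

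**Figure D3:**
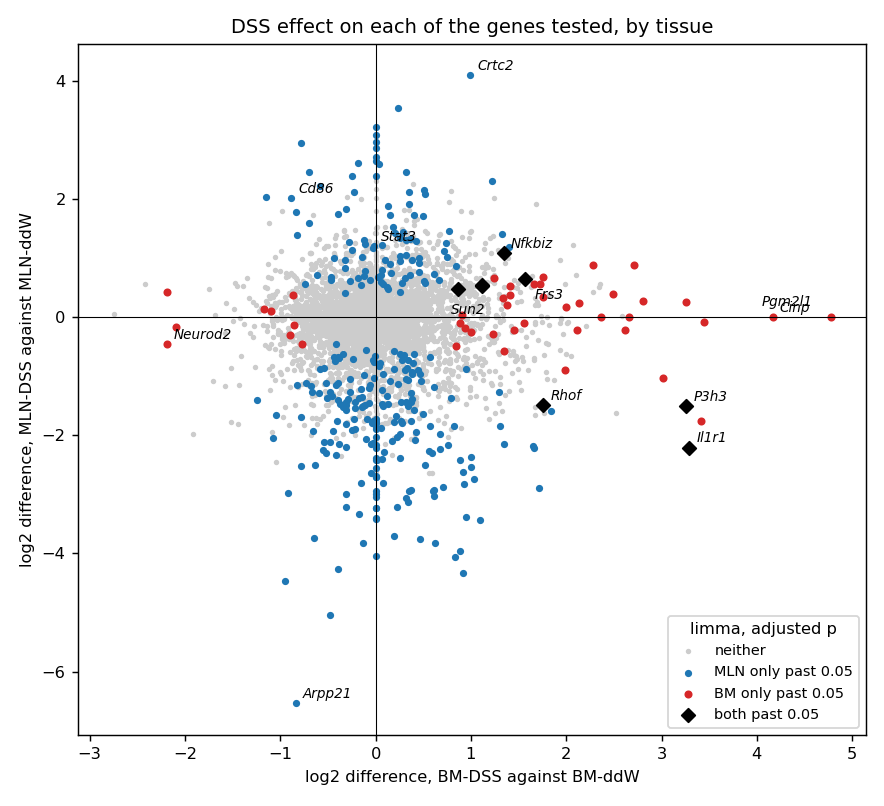
Log2 difference with DSS of each tested gene in BM (horizontal axis) and MLN (vertical axis); colours show in which tissue the limma adjusted p was under 0.05. Most called genes lie near one axis, and 8 genes (diamonds) passed in both tissues.

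MPP2 of lymph node and bone marrow were compared without DSS (MLN-ddW, n = 6, against BM-ddW, n = 4). Of transcription factors known from stem cells, lower in MLN were Meis1 at 7.19 ± 7.92 against 696 ± 123 (−6.93 ± 0.78) and Mecom at 2.15 ± 1.25 against 173 ± 65.2 (−5.78 ± 0.48). Lower too were Hlf at 22.0 ± 8.88 against 145 ± 39.5 (−2.73 ± 0.28) and Erg at 0.430 ± 0.534 against 7.29 ± 3.03 (−2.54 ± 0.40). Also lower were the carbonic anhydrases Car1 at 0.988 ± 1.89 against 1727 ± 1475 and Car2 at 137 ± 99.2 against 3474 ± 954. Higher in MLN were Ciita at 1104 ± 146 against 11.6 ± 5.50 (6.55 ± 0.29) and H2-Aa at 244 ± 33.9 against 0.342 ± 0.684 (7.62 ± 0.41). Others were Pax5 at 102 ± 19.7 against 3.14 ± 4.52 (5.32 ± 0.55) and Dntt, the terminal transferase of lymphoid progenitors, at 124 ± 29.6 against 2.37 ± 3.94 (5.83 ± 0.58). Among the named genes higher in MLN, the largest differences were in Kmt2a, a histone methyltransferase, at 1119 ± 134 against 3.68 ± 7.37 (9.13 ± 0.54), Thg1l at 491 ± 144 against 0.342 ± 0.684, Top2a at 362 ± 96.6 against 0.335 ± 0.670 and Lsm11 at 613 ± 228 against 1.95 ± 2.44. Because neighbouring genes differed together and ribosomal protein genes were low (Other observations), a value need not measure the messenger of the named gene alone. This limit holds for every comparison. Lower was Trpc6, without a read in MLN-ddW and at least 139-fold below its BM-ddW mean of 384 ± 70.7. Pak1ip1, Klhdc7b and Ncaph2 were at 186 ± 33.4, 166 ± 19.2 and 172 ± 22.9 in BM-ddW and at 0.222 ± 0.545, 0.0721 ± 0.177 and 0.857 ± 1.89 in MLN-ddW.

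**Figure D4:**
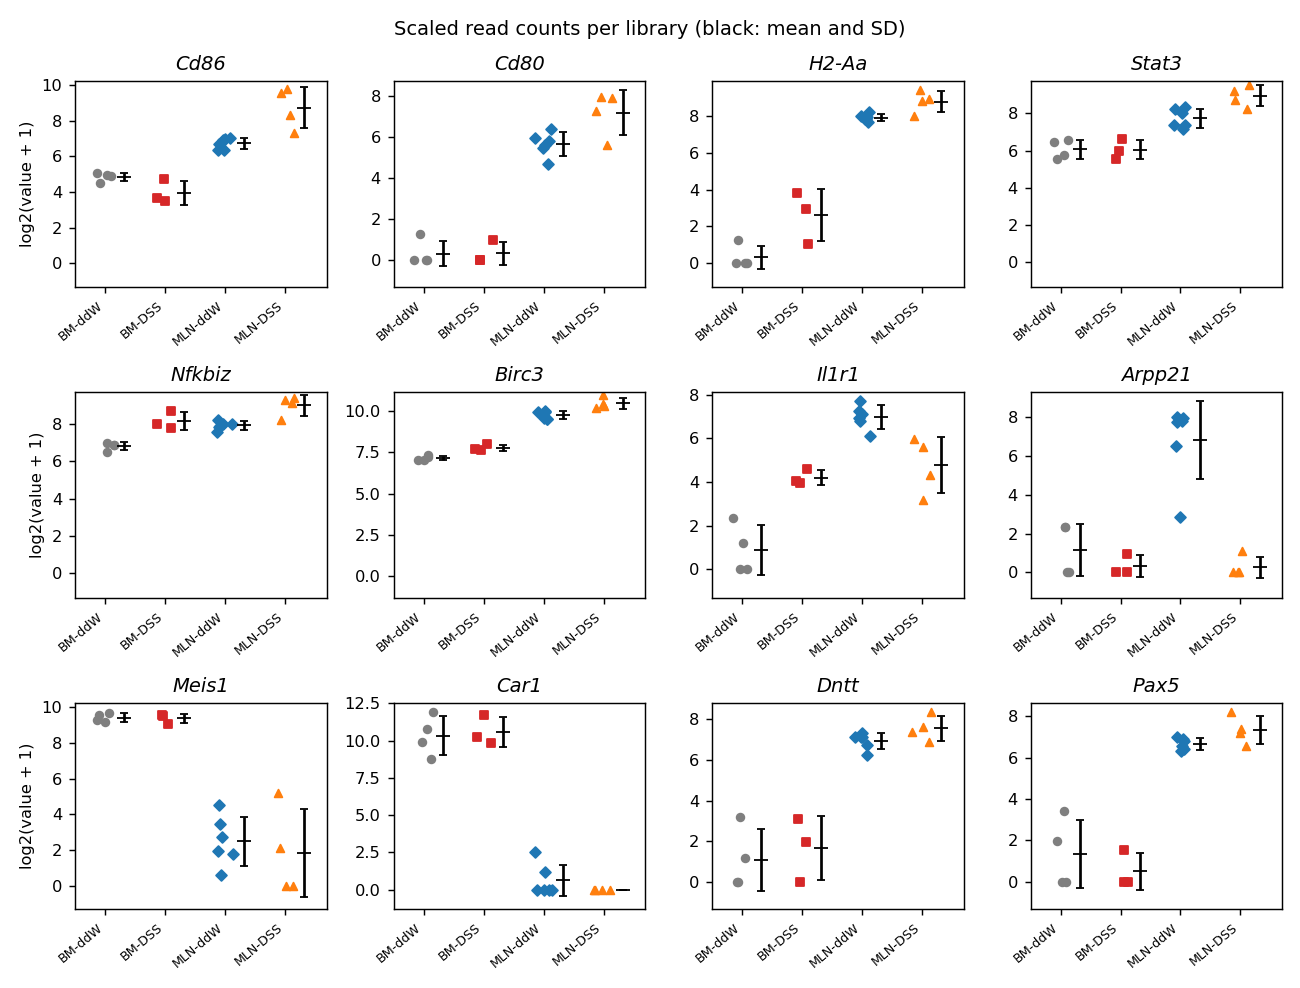
Log2(value + 1) of 12 named genes in each library, by group; points are libraries and black bars are the mean and SD (n = 4, 3, 6 and 4). Cd86, Stat3 and Nfkbiz are higher and Il1r1 and Arpp21 lower in MLN-DSS than in MLN-ddW, and Meis1 and Car1 are low and Dntt and Pax5 high in both MLN groups.

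By list, 5 of 6 tested genes of HSC and MPP identity were lower in MLN (camera adjusted p = 0.0893), as were 6 of 6 erythroid genes (0.0883) and 7 of 7 of ribosome biogenesis and MYC targets (0.0893), for example Nop2, at 76.4 ± 21.9 against 209 ± 33.9. Of all genes tested, 87.3% were called in this comparison (1859 higher, 1932 lower), so most members of any list would be called. Of 6 listed genes of MHC class II and antigen presentation, 5 were tested and 4 were higher. This was the 1 list that passed (camera adjusted p = 0.0447, and 0.222 with an estimated correlation). H2-Eb1, another class II gene, was not higher. It was at 0.254 in MLN-ddW and 2.99 in BM-ddW, below the floors of 2.75 and 3.73. Higher members were also the majority in the NF-kB and TLR list, with 6 of 7 higher and 1 lower (Birc3 at 856 ± 144 against 141 ± 12.6; Ier3 without a read in BM-ddW and at least 4.24-fold higher). The same held for the mast cell and basophil list, with 4 of 5 higher and 1 lower. Of 4 lymphoid priming genes, 3 were higher (Dntt, Ebf1 and Rag2) and Notch1 was lower, at 9.5996 ± 4.77 against 23.1 ± 7.85. Of 10 cytokine and growth factor receptors 6 were higher and 1 lower, and Il1r1 was at 133 ± 47.5 against 1.36 ± 1.94. Megakaryocyte and platelet genes divided into 4 lower (Gp5 at 0.333 ± 0.517 against 113 ± 37.7; Gp1bb without a read in MLN-ddW and at least 5.83-fold lower) and 2 higher (Fli1 at 105 ± 12.7 against 3.19 ± 1.92 and Tubb1 at 118 ± 34.1 against 29.3 ± 13.5). Lower members were the majority among 8 glycolysis genes (6 lower, 0 higher) and 9 of oxidative phosphorylation (6 and 2). So they were among 8 cytosolic ribosomal proteins (5 and 1; Rpl13 at 70.5 ± 20.8 against 376 ± 61.0), 8 of cholesterol synthesis (5 and 1) and 8 of migration (5 and 2). Genes of the interferon response (5 higher, 4 lower of 9), S phase (7 and 7 of 15), and G2 and M phase (5 and 7 of 14) went both ways. So did those of monocytes (4 and 2 of 8), neutrophils (3 and 2 of 5), TLR signalling (3 and 2 of 6) and p53 (4 and 2 of 6), and 3 of 5 immediate early genes were higher. Over the list alone these counts were the same, but for 3 higher monocyte genes. The MHC class II list did not pass without BM-ddW 1 (adjusted p = 0.0619) or MLN-ddW 4 (0.0518), with pseudocount 0.1 (0.0679), or without a filter (0.0860). Notch1 did not pass without BM-ddW 1, BM-ddW 2, MLN-ddW 1 or MLN-ddW 5 (0.0507 to 0.0764).

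Marker scores of other cell types differed for all 8 lists (exact permutation p = 0.00952, the smallest that 6 against 4 libraries can give, and the same adjusted). The scores rested on few listed genes: 2 each for plasma cells, lymph node stroma and epithelium, and 3 each for T cells and endothelium. There were 4 each for B cells and dendritic cells, and 5 for NK and innate lymphoid cells. The listed genes were chosen in a way tied to tissue, with 99.8% at a p under 0.05 in DESeq2. A difference in every list was thus largely built in and is not independent evidence. Scores were higher in MLN-ddW for B cells (6.73 ± 0.23 against 2.83 ± 0.66), T cells (6.405 ± 0.20 against 2.81 ± 0.09), NK and innate lymphoid cells (4.30 ± 0.28 against 2.31 ± 0.26), plasma cells (3.57 ± 0.67 against 0) and dendritic cells (3.13 ± 0.49 against 0.29 ± 0.24). They were lower for lymph node stroma (5.55 ± 0.30 against 6.66 ± 0.17), endothelium (5.64 ± 0.21 against 6.28 ± 0.16) and epithelium (3.94 ± 0.34 against 5.04 ± 0.48). Among single markers, Fcer2a, the low-affinity IgE receptor of B cells, was at 783 ± 238 against 6.92 ± 3.65, and Cd6, a T cell receptor partner, at 302 ± 35.3 against 13.4 ± 5.80. Skap1 had no read in BM-ddW and was at least 8.16-fold higher, and Cd4 was at 69.1 ± 20.6 against 25.6 ± 8.97. Cd79b, a part of the B cell receptor, was lower, at 27.5 ± 4.63 against 70.4 ± 33.4 (−1.22 ± 0.41, adjusted p = 0.0105; 0.0535 without BM-ddW 4). Malat1, a nuclear RNA often raised in damaged cells, was higher in MLN-ddW as well, at 37746 ± 3318 against 27223 ± 2268 (exact permutation p = 0.00952).

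In all, 3791 of 4344 genes passed, 1859 higher and 1932 lower in MLN-ddW. In edgeR 3724 passed (1943 higher, 1781 lower), of which 3597 were shared. The listed genes had been chosen in a way tied to this difference: in a DESeq2 test of MLN against BM over all libraries, 99.8% of the 4993 genes had a p under 0.05, so the share that differed is not independent evidence. TMM scaling moved the log2 differences by a median of 0.14 per gene, and their median over all genes from −0.29 to −0.13. With a filter of at least 50 in 3 libraries, which tests fewer genes, the count was 2509.

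The tissues were compared with DSS as well (MLN-DSS, n = 4, against BM-DSS, n = 3). Meis1 was lower in MLN, at 9.805 ± 17.4 against 671 ± 115, as were Hlf at 15.8 ± 2.49 against 346 ± 66.1 and Mecom at 3.00 ± 2.46 against 175 ± 41.3. Car1 and Igf2r, the receptor of insulin-like growth factor 2, had no read in MLN-DSS and were at least 593-fold and 89.8-fold below their BM-DSS means of 1851 ± 1385 and 281 ± 61.8. Muc13, a mucin, was at 0.498 ± 0.996 against 1860.4 ± 373, and Angpt1, a ligand that supports stem cells, at 1.11 ± 1.29 against 495 ± 53.2. Higher in MLN were Top2a, at 982 ± 448 against 0.664 ± 0.576, Slc39a8, a zinc transporter, at 424 ± 148 against 0.640 ± 1.11, Neurod2 at 857 ± 216 against 2.44 ± 1.72 and Clec2i at 380.1 ± 18.2 against 1.28 ± 2.22. Kmt2a and Usp42 had no read in BM-DSS and were at least 249-fold and 109.6-fold higher in MLN-DSS. Of 6 listed genes of MHC class II and antigen presentation, 5 were tested and all 5 were higher (camera adjusted p = 0.00352, and 0.0665 with an estimated correlation). Among them were Cd86 at 523 ± 343 against 15.6 ± 8.20 and Ciita at 1703 ± 816 against 20.7 ± 7.78. Of 8 cytosolic ribosomal protein genes 7 were lower (camera adjusted p = 0.0419; adjusted p = 0.163 with an estimated correlation), among them Rpl13 at 76.7 ± 28.2 against 346 ± 17.6. Over the list alone the counts of both lists were the same. Of all genes tested, 72.1% were called in this comparison. The ribosomal list did not pass without BM-DSS 2 (adjusted p = 0.0548), MLN-DSS 3 (0.0581) or MLN-DSS 4 (0.0516), or with pseudocount 0.1 (0.0532). Malat1 was higher in MLN here too, at 45583 ± 13479 against 21274 ± 3571 (exact permutation p = 0.0571, the smallest that 4 against 3 libraries can give).

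In all, 3133 genes passed, 1505 higher and 1628 lower in MLN-DSS, and edgeR called 3049 (1625 higher, 1424 lower), of which 2905 were shared; with the filter of at least 50 in 3 libraries the count was 2068. The tissue differences with and without DSS had a Pearson correlation of 0.910 and a Spearman correlation of 0.916 across genes, and 1343 genes were higher and 1401 lower in MLN in both. The listed genes were chosen in a way tied to the tissue difference over all libraries, so this likeness is largely built in. No list call of any comparison held with an estimated correlation in camera. Marker scores differed in the same directions as without DSS, for example B cells at 6.72 ± 0.39 against 2.30 ± 0.09, but 4 against 3 libraries cannot give an exact permutation p under 0.0571, which all 8 lists had.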

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

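The search for single samples far from the rest was narrowed, after a wider search had been seen, to the groups of the comparisons in which a gene is named; the tests of DSS effects between tissues were planned. In groups of 4 to 10 libraries, the gap of the highest or lowest library to its nearest neighbour was set against the range of the group (Dixon's 95% critical values). This singled out 30 values in 208 groups, against 43 in the wider search. Chance singles out about 1 in 20 groups, or 5%, and many of these values are single reads in a group otherwise at 0.

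In MLN-ddW 1 the B cell marker score was 6.28 (others 6.70 to 6.92) and the NK and innate lymphoid score 4.83 (others 4.08 to 4.35). The same library had Kif4 at 395 (others 12.97 to 39.1), Skap1 at 54.9 (others 21.8 to 30.9), and Ccm2, Car1 and Ncaph2 at 4.71 each, so 7 of the 30 values came from this library, which had the fewest reads. Fxyd6 was at 41.1 in MLN-ddW 5 (others 0.865 to 13.9), Kdr at 67.5 in MLN-ddW 6 (others 27.3 to 40.3) and Brsk2 at 15.9 in MLN-ddW 2 (others 0 to 5.07). Single low values above 0 were those of Pak1ip1 in MLN-ddW 5 (1.33), Klhdc7b in MLN-ddW 6 (0.432) and Eda2r in MLN-ddW 4 (1.86), with the other libraries of the group at 0.

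In MLN-DSS 1, Kmt2a was at 1356 (others 524 to 621), and Arpp21 (1.12) and Ipcef1 (2.23) had reads in that library alone of its group. In MLN-DSS 3, Klf6 was at 379 (others 696 to 757), Ccm2 at 6.43 (others 17.8 to 18.9) and Heatr1 at 9.64 (others 0 to 0.996). In MLN-DSS 4, Meis1 was at 35.9 (others 0 to 3.35) and Muc13 at 1.99. In BM-ddW 3, Neurod2 was at 46.5 (others 6.96 to 10.7), Dntt at 8.21 (others 0 to 1.27), and Cd80, H2-Aa and Thg1l at 1.37 each. In BM-ddW 4, Kmt2a was at 14.7 and Top2a and Pgm2l1 at 1.34 each, and in BM-ddW 1 Cinp was at 0.994, with the other libraries at 0.

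The effect of DSS differed between the tissues, by the interaction term of limma, for 30 of the named genes; values are log2 differences of the MLN effect from the BM effect, with adjusted p between 2.7e-04 (Pgm2l1) and 0.0496 (Hlf). Lower effects in MLN were found for Arpp21 (−5.70), Il1r1 (−5.51), Eif2b3 (−5.25), Glg1 (−5.18), Hectd3 (−4.84), Pgm2l1 (−4.77), P3h3 (−4.77), Ipcef1 (−4.57), Btbd19 (−4.44), Heatr1 (−4.22), Cinp (−4.16), Rif1 (−4.05), Kif2c (−3.53), Dram2 (−3.53), Slc6a20a (−3.52), Mpzl3 (−2.53) and Hlf (−1.63). Higher effects were found for Scn3b (3.73), Muc5b (3.18), Ccm2 (3.08), Cd86 (2.90), Atp5l (2.71), Tmem57 (2.30), Fabp5 (2.22), Eno2 (1.63), Copa (1.57), Klf6 (1.42), Wnk4 (1.30), Chic1 (1.23) and Slc23a2 (1.20). Pgm2l1 and Cinp had no read in any MLN library, so their difference rests on BM alone. The call of Arpp21 ended without BM-DSS 1 (adjusted p = 0.0747) and that of Hectd3 without BM-DSS 1 or 2 (0.0673 and 0.0522). Those of Ccm2, Scn3b, Atp5l, Hlf, Fabp5, Eno2 and Copa ended without several libraries each, with the highest adjusted p, 0.103, 0.115, 0.113, 0.166, 0.131, 0.125 and 0.0921, without BM-DSS 1. Those of Muc5b and Klf6 did too, with the highest without BM-DSS 2 (0.121) and BM-DSS 3 (0.142). The alternatives were not run on the interaction of Btbd19, Chic1, Cinp, Dram2, Heatr1, Mpzl3, Rif1, Slc23a2, Slc6a20a and Wnk4. In edgeR, adjusted p was 1.00 for Ccm2 and Pgm2l1, 0.993 for Ipcef1, 0.5257 for Arpp21, 0.318 for Scn3b and 0.0607 for Klf6.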

How the results depend on the processing

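Alternatives chosen after seeing the data were the edgeR test on recovered reads with deposited size factors or TMM, TMM and RLE scaling in limma, the filter of at least 50, other pseudocounts for the lists, every alternative for the marker lists, and left-out libraries for the correlations across genes. Counts of genes under 22 alternatives (21 for the interaction) were within 1.5 times the reported count in 18 for DSS in MLN, 18 for DSS in BM, 21 for each tissue comparison and 19 for the interaction. The others were as follows. With only the groups compared in the model, 155 genes passed for DSS in MLN and 14 for DSS in BM. With replicate numbers as blocks, 171, 22 and 55 genes passed for DSS in MLN, DSS in BM and the interaction, and in DESeq2 476, 114 and 228. Limma-voom called 501 genes for DSS in MLN, and with sample quality weights 452 for DSS in BM. The filter of at least 50 in 3 libraries, which tests fewer genes, left 2509 genes for MLN-ddW against BM-ddW and 2068 for MLN-DSS against BM-DSS.

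Leaving out each library in turn gave 231 to 403 genes for DSS in MLN, 22 (without BM-DSS 1) to 129 (without BM-ddW 1) for DSS in BM, 3520 to 3703 and 2647 to 3079 for the tissue comparisons without and with DSS, and 37 (without BM-DSS 1) to 234 (without MLN-DSS 3) for the interaction. DSS in BM gave 25 without BM-DSS 2, and the interaction 81, 57 and 64 without BM-ddW 3, BM-DSS 2 and BM-DSS 3.

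With an estimated correlation, camera passed 0 lists for DSS in MLN, 0 for DSS in BM, 0 for MLN-ddW against BM-ddW and 0 for MLN-DSS against BM-DSS. Fry passed 3, 19, 15 and 2 lists for DSS in MLN, MLN-ddW against BM-ddW, MLN-DSS against BM-DSS and the interaction; neither of its p-values compares a list with other genes. For MLN-ddW against BM-ddW, 0 lists passed without a filter, 0 with replicate blocks and 0 with pseudocount 0.1; for MLN-DSS against BM-DSS, 7 passed with blocks and 1 with pseudocount 0.1. Without 1 library, lists passing numbered 0 (without MLN-DSS 4) to 1 for DSS in MLN, 0 (without BM-ddW 1 or MLN-ddW 4) to 1 for MLN-ddW against BM-ddW, and 1 (without BM-DSS 2, MLN-DSS 3 or MLN-DSS 4) to 2 for MLN-DSS against BM-DSS. Across genes, the correlation of tissue differences with ddW and with DSS stayed high in every alternative run for it, and that of the DSS changes in the tissues stayed close to 0, with either sign. The latter ranged from −0.00398 to 0.0119 (Pearson) and from 0.0247 to 0.0311 (Spearman) over 3 processing alternatives, and from −0.0225 to 0.0249 and from −0.0120 to 0.0686 with 1 library left out. The unmoved marker list counts are no evidence of stability for DSS in BM and for MLN-DSS against BM-DSS, where p cannot go under 0.0571.

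Of the named genes with a call, 19 of 33 lost it in some alternative for DSS in MLN, 16 of 18 for DSS in BM, 2 of 38 and 0 of 21 for the tissue comparisons without and with DSS, and 16 of 20 for the interaction. None of these changed direction. In some alternative 2, 2 and 1 named genes without a call gained one for DSS in MLN, DSS in BM and the interaction. Replicate blocks ended 8 of 33, 12 of 18 and 12 of 20 calls for DSS in MLN, DSS in BM and the interaction. Among them were Il1r1 (adjusted p = 0.0876), Tlr2 (0.0590), Top2a (0.0649), Ccr3 (0.0854) and Hk1 (0.0600) in MLN. In BM they included Il1r1 (0.0638), Nfkbiz (0.0649), Neurod2 (0.0649), Rif1 (0.0629), Wnk4 (0.0817), H2-Aa (0.149) and Lss (0.119), and for the interaction Glg1 (0.0544), Hectd3 (0.0736) and Arpp21 (0.0757). With genes detected as a covariate, which kept the counts within 1.5 times, 60.9% of calls for DSS in MLN were higher, against 32.8%.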

Other observations

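Tests chosen after the results were seen were those of genomic DNA, of the choice of listed genes, of names out of register, of mature B cells and of lymphoid priming, the fit without MLN-ddW 4 to 6, and the interval of the ribosomal protein median; the neighbour tests were set before correlations were computed but after runs of neighbouring genes had been noticed.

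Other splits of the same libraries into groups of the same sizes tested whether chance can be excluded. For DSS in MLN, 1 of 100 splits, the real one, gave as many genes (302, highest other 77). That argues against chance for this count, if the libraries are independent. For the interaction it was 1 of 100 drawn from 7350 (125, highest other 64). The interaction splits exchanged the drinks within each tissue, so they stand for no DSS effect in either tissue. They cannot decide whether chance gives an interaction where DSS acts alike in both tissues. The tissue comparisons gave 1 of 100 without DSS (3791; highest other 1657) and 1 of 35 with DSS (3133; highest other 1958), but the listed genes were chosen in a way tied to tissue, so these splits do not bear on chance. For DSS in BM chance is not excluded: 2 of 35 splits gave at least the 52 genes of the real one, and the split of BM-ddW 2, 3 and 4 against BM-ddW 1 with the 3 BM-DSS libraries gave 77.

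The first pattern is that neighbouring genes differed together. For MLN-ddW against BM-ddW, differences of neighbouring listed genes had a Spearman correlation of 0.852 where the genes overlap (286 pairs), 0.780 at gaps of 1 to 10 kb (900), 0.453 at 10 to 100 kb (1267; highest of 10000 permutations 0.135, p = 0.0001, the smallest they can give) and 0.0479 at 100 kb to 1 Mb. Reads shared by overlapping genes are argued against as the whole cause by pairs at least 10 kb apart (0.203), but that value barely passes the bound of 0.2 written in advance, and the argument rests on the pairs at 10 to 100 kb, a condition added after the values were seen. The MLN-ddW and BM-ddW libraries did not overlap for 2944 tested genes. Chance would give 528.1 on average over all 55450 genes of GENCODE M21. If genes vary independently, that argues against even coverage of genomic DNA as the whole cause, also where genes were chosen by tissue. Neighbouring genes differed together, and the spread of the chance number was not computed, so the count alone does not exclude even coverage. Genomic DNA as a part of the reads, or unevenly covered, was not tested. Regional activity of gene neighbourhoods may be a candidate explanation, as the correlation was 0.00610 for pairs 1 to 5 Mb apart, and stays a hypothesis found and tested on the same data.

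The second pattern is the low values of housekeeping genes. Ribosomal protein genes had a median value of 13.7 against 37.2 for all listed genes. Per kb of exon they stood at percentile 41.4 (interval of the median 14.7 to 95.5, coverage 97.9%). A percentile under 50 had been written in advance as arguing against short length. The value met that bound, but not by more than its spread, so short length stays open, as does the choice of the listed genes, which hold 10 of the 58 genes of the fixed list. Of tested HSC and erythroid members, 91.7% (11 of 12) were lower in MLN-ddW against 44.5% of all genes (Fisher exact p = 0.00179). This cannot decide whether gene names are out of register with their values. Neighbouring genes differed together, so names shifted to a neighbouring gene would keep most directions. Both lists had also been seen to go one way before the test was chosen. No biological explanation was tested.

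The third pattern is the higher level of lymphocyte genes in lymph node libraries. Of the 15 called members of the B cell, T cell, NK cell and MHC class II lists, 13 were higher and 2, Cd79b and Klrg1, lower. In MLN-ddW 1, which had 301956 reads over the listed genes, 80.0% of them (12 of 15) were above every BM library. This met the bound written in advance, but not by more than its spread. More reads in these libraries are argued against by a fit without MLN-ddW 4 to 6, since MLN-ddW 1 to 3 had 301956 to 431329 reads against 359737 to 459875 in BM-ddW. In it 12 of the 13 stayed called higher, with a median log2 difference of 4.74 against 4.83 with all libraries. Il13 lost its call (adjusted p = 0.0899), at 1.26 ± 0.66 against 1.54 ± 0.54. Mature B cells could be a source, although the sort for lineage-negative, Sca-1-positive and c-Kit-positive cells would remove them; Cd79b was lower in MLN-ddW (−1.22) and H2-Eb1 was at 0.254 against 2.99, but because ribosomal protein genes are also low here, a level need not follow abundance and the source stays open. Lymphoid priming of lymph node progenitors stays open too: 3 of 4 priming genes were higher, as were 6 of 7 B and T cell members, and both sources predict this. Tissue, the difference the design names, stays among the open explanations.

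Several other features were seen. Of calls for DSS in MLN, 82 of 203 lower genes had a called neighbour of the same direction within 100 kb (mean of 1000 permutations 10.7, highest 28). Olfactory and vomeronasal receptor genes numbered 76 among the listed genes, of which 56 had a group mean of at least 10 and 13 of at least 100, with a highest mean of 730.1. Genes whose groups did not overlap numbered 248 for DSS in MLN (5.71%; chance gives 0.952%), 727 for DSS in BM (16.7%; chance 5.71%), 2944 for MLN-ddW against BM-ddW (67.8%; 0.952%) and 2740 for MLN-DSS against BM-DSS (63.1%; 5.71%). The listed genes were chosen in a way tied to tissue, so the shares between tissues are largely built in. Chance shares are means per gene. Neighbouring genes differed together, so an excess over these shares is no test of an effect. For DSS in BM the splits did not exclude chance.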
